A study of Mus musculus with 12 samples.

How the data were processed

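Poly(A)-selected RNA from mouse liver was sequenced in 12 libraries. Per the labels' protocols, tissue was homogenised in a bullet blender, RNA was extracted with RNeasy columns and an on-column DNase step, mRNA was captured on poly-T beads, and cDNA was primed with random hexamers. Per the labels, the mice were 16 weeks old, of both sexes, and either 129S1/SvImJ (wild type) or 129/Sv-Cyp2e1tm1Gonz/J (Cyp2e1 knockout), with 3 biological replicates in each of 4 groups. The deposited table holds raw counts per gene for each library, and its values were checked to be whole numbers whose totals differ between libraries. The submitters' processing notes name HISAT2 2.0.5, DESeq2 and the mm39 genome build without saying what each was used for. The counting program and the strand setting are not given in the sources used here. The table also gives Ensembl gene identifiers, symbols, mm39 positions, gene length and biotype. Each column was assigned to its sample by the library number that the labels and the column names share, and the sex and genotype of each column were checked against Y-linked genes, Xist and Cyp2e1.

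Total counts per library ran from 15167730 to 25082532. Genes were kept by edgeR's filterByExpr with default settings on the 4 groups, which left 14003 of 56748 genes, holding 99.9% of the counts. The biological coefficient of variation was 25.9%. At this depth a gene with 0 counts in a group is given a floor of 3 counts over the group, and a fold against it is a lower bound. Where a group had 1 to 3 counts, the ratio of counts is given with an exact 95% counting interval. Pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 15.8 to 141).

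Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, a model with 1 mean per group fitted to all 12 libraries (8 residual degrees of freedom, prior degrees of freedom 5.22), and the quasi-likelihood F test (glmQLFit and glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over the genes tested, within each contrast, and a gene was called at an adjusted p under 0.05. The 6 contrasts were knockout against wild type in females, in males and as the mean of both sexes, the difference of that effect between the sexes, and male against female in wild type and in knockout mice. Standard errors were back-calculated as the absolute log2 fold change over the square root of the quasi-likelihood F statistic, and are approximate. Levels are CPM of TMM-scaled library size, and log2 CPM used a prior count of 2.

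Genes were named by a rule. Cyp2e1 came first. For each knockout contrast the 6 largest changes each way followed, among called genes with average log2 CPM of at least 1, a symbol other than Gm with a digit or one ending in Rik, and every knockout library above (or below) every wild type library of its sex. Up to 4 members of smallest adjusted p were added for each gene list with a called member. For the difference between sexes and for the sex contrasts the 4 largest each way were taken. Genes outside the rule are given as chosen after their values were seen. Some genes that the rule takes are not reported here one by one, and they stay in all fits, list tests and counts of genes.

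A set of 34 gene lists was tested in each contrast with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. Cyp2e1 itself is in none of them. An estimated correlation and the rotation test fry were alternatives. The lists were drug and steroid P450s (Cyp1 to Cyp3 families), Cyp4 fatty acid hydroxylases, PPARalpha targets and fatty acid oxidation, ketone body metabolism, lipogenesis, cholesterol biosynthesis, bile acid synthesis and transport, antioxidant and Nrf2 targets, glutathione S-transferases, and glucuronidation, sulfation and acetylation. They further were alcohol and aldehyde metabolism, gluconeogenesis and fasting response, methionine and one-carbon metabolism, pericentral and periportal hepatocyte markers, ER stress and integrated stress response, acute phase response, interferon response, the nuclear-encoded and the mitochondrially encoded respiratory chain, and heme synthesis and iron handling. The rest were the growth hormone and IGF axis, male-biased and female-biased liver genes, circadian clock and output, cell cycle, markers of stellate cells and fibrosis, Kupffer cells and macrophages, lymphocytes and neutrophils, sinusoidal endothelium, cholangiocytes, erythroid cells, and adipose, pancreas and muscle, and sex chromosome control genes. For each list the members past the threshold were counted over all genes tested and adjusted over the list alone.

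Called genes within 10 Mb of Cyp2e1 and on each chromosome were compared with the rest by a two-sided Fisher's exact test. The length slope of a library is the slope of its log2 CPM deviation from the mean of all libraries on log2 gene length. It was taken over 9325 genes with a mean log2 CPM above 2 and a GC value. Groups were compared in it by an exact permutation test. Principal components were taken from the log2 CPM of the 2000 most variable genes. GC content came from the GENCODE M21 annotation of GRCm38 by Ensembl identifier and covered 98.6% of the tested genes. Tables were read with the package data.table (1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

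The alternatives were DESeq2 size factors in place of TMM, the DESeq2 1.42.0 Wald test, no filter beyond a total count above 0, a mean CPM of at least 5, only the 6 libraries of the groups compared, the replicate number as a block, and each library left out in turn. Further alternatives removed a smooth trend of each library in gene length and GC content as an offset. This trend was fitted by natural splines with 4 degrees of freedom over all tested genes with a GC value. Others put the length slope into the model as a covariate, or left out the 2 male libraries of lowest length slope. The pipeline was tested on simulated data with 13846 genes (13811 for the sex contrasts). It recovered 26.9% of genes changed 2-fold and 84.8% of genes changed 4-fold in the female contrast, 17.9% and 86.4% in the male contrast, 71.6% and 95.5% for the mean of both sexes, and 0% and 53.0% for the difference between sexes, with 1.30% to 5.41% false calls and 0 gene lists called. The simulated genes were drawn independently, without correlation between genes and without a length slope of the libraries. These rates of false calls therefore do not cover differences that libraries share across genes, and the 0 lists do not test the preset correlation. Sequence reads, alternative splicing and genetic variants between the lines were not analysed here. No column of the count table was left out.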

Results

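Liver RNA was measured by poly(A)-selected sequencing in 16-week-old mice of a pair of inbred 129 lines kept on normal chow and co-housed. The 129/Sv-Cyp2e1tm1Gonz/J line (knockout) carries a targeted allele of Cyp2e1, the cytochrome P450 that oxidises ethanol, acetaminophen and other small molecules, and the 129S1/SvImJ line served as wild type. Each of 4 groups (female wild type, female knockout, male wild type, male knockout) held 3 biological replicates, 12 libraries in all. Because the knockout and the wild type are different lines, each knockout comparison is also a comparison of lines. Total counts per library ran from 15167730 (male knockout replicate 2) to 25082532 (female knockout replicate 3), and 14003 of the 56748 genes listed had enough counts to be tested. Fold changes below are log2 values from edgeR's quasi-likelihood fit to all 12 libraries, ± a standard error back-calculated from its F statistic. Levels are CPM (counts scaled by library size), as mean ± SD of the 3 libraries of a group. Intervals and lower bounds built on counts cover counting error only.

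Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140343652 to 140354900, mm39, protein-coding) was lower in every knockout library than in every wild type library. In wild type females it stood at 6213, 6349 and 7076 CPM, a mean of 6546 ± 464, which was rank 13 among all genes. In knockout females it stood at 230, 323 and 277 CPM (277 ± 46.2), or 4.23% of the wild type mean. Wild type males had 10374, 11480 and 10700 CPM (10851 ± 568, rank 9), and knockout males had 389, 403 and 318 CPM (370 ± 45.6), or 3.41% of the wild type mean. The fold change was -4.56 ± 0.20 in females (adjusted p = 8.87e-08), -4.87 ± 0.21 in males (adjusted p = 4.59e-08) and -4.72 ± 0.14 over both sexes (adjusted p = 6.99e-10). The male and the female effect on Cyp2e1 were not shown to differ (difference -0.31 ± 0.25, adjusted p = 0.43).

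**Figure D1:**
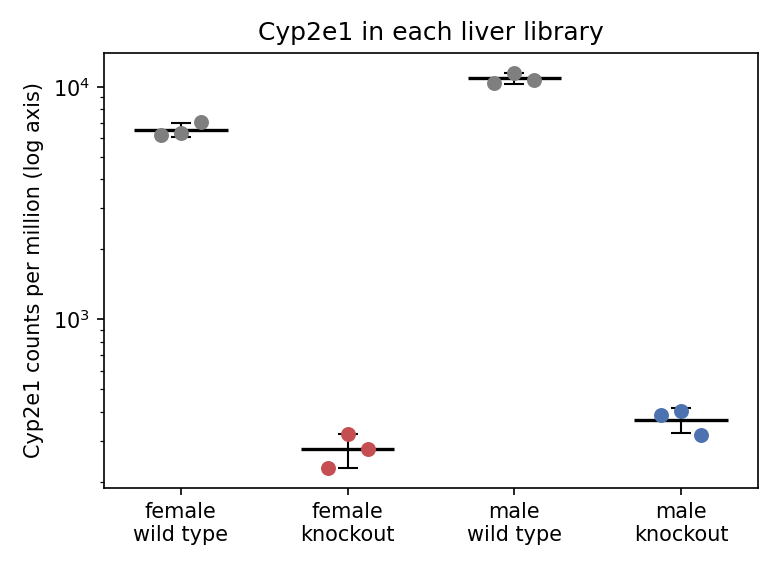
Cyp2e1 level in CPM (log axis) in each of the 12 liver libraries by group, with 1 point per library, a thick line at the mean and bars of 1 SD (n = 3). The 6 knockout libraries lie between 230 and 403 CPM and the 6 wild type libraries between 6213 and 11480 CPM.

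Genes of the sex chromosomes matched the labelled sex of all 12 libraries. Ddx3y, on the Y chromosome, had 828 to 1599 counts in male libraries and 0 or 1 in female libraries. Xist, expressed from the inactive X chromosome, had 1258 to 7917 counts in female libraries and 0 to 2 in male libraries. In a principal component analysis of the 2000 most variable genes, component 1 (55.6% of variance) held the females at -48.4 to -38.8 and the males at 35.5 to 49.3. Component 2 (21.6%) held wild type females at 24.2 to 38.6 and knockout females at -35.5 to -23.1, while male wild type libraries (-16.0, 3.26 and 31.0) and male knockout libraries (-27.3, -17.5 and 18.8) overlapped. The libraries also differed in how the level of a gene moved with its length. This slope, in log2 units per doubling of gene length, was -0.19 ± 0.04 (SD, n = 3) in wild type females, 0.19 ± 0.10 in knockout females, -0.02 ± 0.13 in wild type males and 0.03 ± 0.17 in knockout males. The female groups did not overlap in it (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give) and the male groups did (exact permutation test, two-sided p = 0.8).

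**Figure D2:**
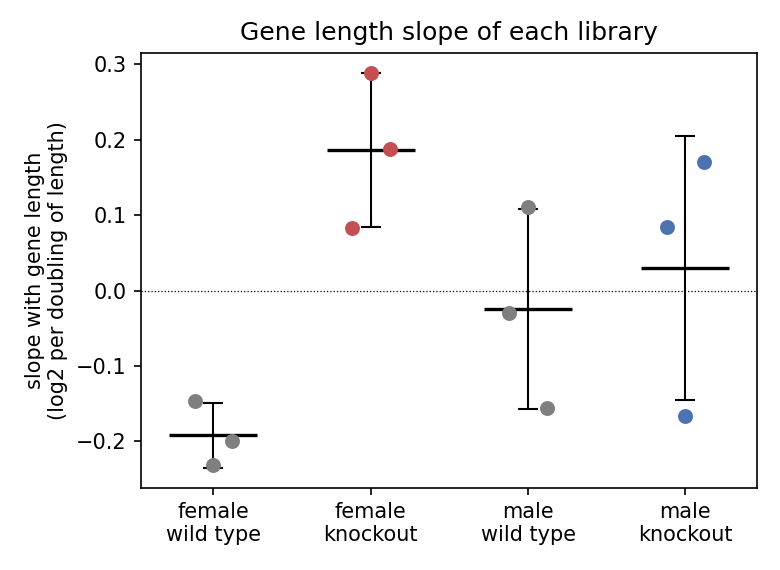
Slope of expression with gene length (log2 units per doubling of length, relative to the mean of all libraries) for each of the 12 libraries by group, with the group mean and bars of 1 SD (n = 3). Wild type females lie at -0.23 to -0.15 and knockout females at 0.08 to 0.29, and the male groups span -0.17 to 0.17 without separating.

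The female comparison asked which liver transcripts differ between female knockout and wild type mice. Next to the loss of Cyp2e1, many transcripts for nuclear-encoded subunits of the mitochondrial respiratory chain (63 of 74), glutathione S-transferases (10 of 20) and enzymes of glucuronidation, sulfation and acetylation (16 of 28) were lower. None of these 3 lists held with an estimated correlation (adjusted p = 0.926, 0.449 and 0.926), while fry called all 3 (adjusted p = 0.0269, 0.000629 and 0.02). With each library's length slope in the model the mean of the respiratory chain list was -0.11 (adjusted p = 0.134). Atp5pb, a subunit of ATP synthase, went from 740 to 294 CPM (-1.33 ± 0.28). Sult1d1, a sulfotransferase, went from 543 to 143 CPM (-1.92 ± 0.35), and Gsta3, a glutathione S-transferase, from 2230 to 1014 CPM (-1.14 ± 0.24). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 635 ± 168 to 171 ± 55.6 CPM (-1.89 ± 0.35, adjusted p = 0.0132), and Nr1d1, a repressor in the circadian clock, rose to 149 ± 26.5 CPM in knockout females (2.90 ± 0.45, adjusted p = 0.0132). Of 14003 genes, 5116 (36.5%) changed, 2479 higher and 2637 lower in the knockout, and 2978 of them by more than 2-fold.

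The count of female calls depended on single libraries and moved with the length slope. Without wild type replicate 2 the count was 5 genes and without knockout replicate 2 it was 4. It was 3956 and 2927 without wild type replicates 1 and 3, and 4227 and 2909 without knockout replicates 1 and 3. By the quasi-likelihood test 6797 genes had an unadjusted p under 0.05 in the full fit. That number was 5349 without wild type replicate 2 and 5433 without knockout replicate 2, so it fell far less than the calls did. Gene length and GC content together accounted for 35.0% of the variance of the female effect across genes. With each library's length slope in the model 10 genes were called, and with the length and GC trend removed 3182 were, 1179 higher and 2003 lower. Of genes named below, Abcc2 (-0.12), Aldh5a1 (-0.038), Cpt1a (-0.023), Orm1 (0.064) and Sel1l (-0.0066) turned sign with the slope in the model and Sult3a1 (0.22) with the trend removed. Cyp2e1, Gm10503, Gm6135 and Nlrc5 were the 4 genes called in each of the 6 fits with 1 library left out, and all other female calls named here were lost in at least 1 of them. The last 3 were chosen after their values were seen. Nlrc5 (ENSMUSG00000074151, chromosome 8, 95160984 to 95253900), a regulator of MHC class I genes, rose from 2.07 to 10.2 CPM (2.30 ± 0.24, adjusted p = 0.001). The lncRNA Gm6135 (ENSMUSG00000106069, chromosome 3, 133494950 to 133497318) fell from 141 ± 68.4 to 11.9 CPM (-3.56 ± 0.41, adjusted p = 0.00249), and of these 4 genes it alone lost its call with each library's length slope in the model (-1.76, adjusted p = 0.473). The lncRNA Gm10503 had 5.35 ± 0.125 CPM in wild type females and 0 counts in the knockout females, at least 127.6-fold lower against a floor of 3 counts over the group.

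The nuclear-encoded respiratory chain list had 63 of 74 measured members lower, 0 higher and 11 that did not pass (65 lower adjusted over the list alone), with a mean of -1.13. Atp5k (-1.65 ± 0.34), Ndufa5 of complex I (-1.30 ± 0.27) and Atp5c1 (-1.06 ± 0.21) were among them. By camera the list moved against all other genes with adjusted p = 8.62e-20, and with adjusted p = 0.926 with an estimated correlation. The length slope of the libraries parted the same groups. The list's mean was -0.77 (adjusted p = 5.39e-17) with the length and GC trend removed from each library and -0.11 (adjusted p = 0.134) with each library's length slope in the model. In the mitochondrially encoded respiratory chain list 1 of 13 members fell (0 adjusted over the list alone), mt-Atp8 (-1.67), which turned to 0.04 with the length and GC trend removed.

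In the list of glutathione S-transferases 10 of 20 members fell and 0 rose (also 10 adjusted over the list alone; camera adjusted p = 0.00206; adjusted p = 0.449 with an estimated correlation), among them Gsta1 (-2.63 ± 0.49), Gstp1 (-0.88) and Gstt1 (-0.72). In the list of glucuronidation, sulfation and acetylation 16 of 28 members fell and 1 rose (the same counts adjusted over the list alone; camera adjusted p = 0.000798; adjusted p = 0.926 with an estimated correlation), among them Ugt2b37, from 34.1 ± 20.9 to 5.17 CPM (-2.72 ± 0.38), and Ugt2b36 (-1.34). With the length and GC trend removed both calls ended, with means of -0.31 for glutathione S-transferases (adjusted p = 0.218) and 0.24 for glucuronidation, sulfation and acetylation (adjusted p = 0.339). With each library's length slope in the model they were -0.62 (adjusted p = 9.92e-06) and -0.35 (adjusted p = 0.0076). Of 42 drug and steroid P450s, which do not include Cyp2e1, 2 rose and 15 fell. Camera did not call the list (adjusted p = 0.0589, and 0.952 with an estimated correlation), while fry did (adjusted p = 0.0269). Cyp3a44 (-1.68) was lower and Cyp2u1 (2.10 ± 0.34) higher. Cyp3a41b (-1.36) fell too, but its reads cannot be told from those of Cyp3a41a with certainty, since the counting program is not given in the sources used here. Of 29 antioxidant and Nrf2 targets 2 rose and 9 fell, with Nqo1 from 21.5 to 7.30 CPM (-1.56 ± 0.24), Cbr1 (-1.26 ± 0.19), Prdx1 (-1.44 ± 0.30) and Mgst1 (-1.14). Fry called this list (adjusted p = 0.00601) and camera did not (adjusted p = 0.135). Of 20 genes of alcohol and aldehyde metabolism 1 rose (Aldh5a1, 0.92) and 3 fell (Adh7, -1.05; Aldh1a7, -0.79; Akr1a1, -0.60).

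Lipid and sterol genes moved in both directions. Camera called no female list beyond the 3 above. Since 36.5% of all tested genes were called in females, a count near that share does not set a list apart. Of 21 lipogenesis genes 5 fell and 1 rose, with Thrsp from 2724 to 611 CPM (-2.16 ± 0.38), the fatty acid elongase Elovl6 (-1.41 ± 0.23) and malic enzyme Me1 (-1.03) lower. Of 37 PPARalpha targets and genes of fatty acid oxidation 3 rose and 10 fell, with the fatty acid transporter Cd36 from 65.9 to 23.4 CPM (-1.49 ± 0.21) lower and Cpt1a (1.31 ± 0.33) higher. Of 12 Cyp4 fatty acid hydroxylases 1 rose, Cyp4a31 (1.22 ± 0.28), while Cyp4a10 (166 and 170 CPM, 0.04 ± 0.30, adjusted p = 0.929) and Cyp4a14 (187 and 242 CPM, 0.37 ± 0.43, adjusted p = 0.509), chosen after their values were seen, did not pass. Of 24 cholesterol biosynthesis genes 4 rose and 5 fell, with Tm7sf2 (-0.92) lower and the regulator Srebf2 (1.34 ± 0.30) higher. Of 26 genes of bile acid synthesis and transport 5 rose and 7 fell (6 and 8 adjusted over the list alone), with the canalicular pump Abcc2 (1.41) and Klb (1.23) higher and Cyp7b1 (-1.11) lower. Of 8 ketone body genes 3 rose and 3 fell, with Slc16a6 (1.20) and Bdh1 (0.75) higher and Bdh2 (-0.997) lower. Of 14 gluconeogenesis and fasting genes 2 rose, Irs2 (1.79) and Ppargc1a (0.69), and 1 fell, Slc37a4 (-0.63), and 1 each way adjusted over the list alone.

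Of 19 methionine and one-carbon genes 4 rose and 3 fell, with Cbs (1.47 ± 0.34) higher and Gnmt (-1.07) and Pemt (-0.91) lower. Of 22 pericentral hepatocyte markers 5 rose and 4 fell, with Tbx3 (1.70), Lgr5 (1.12) and Rnf43 (1.10) higher, and of 18 periportal markers 6 rose and 2 fell (7 and 2 adjusted over the list alone), with Cdh1 (1.11), Hsd17b13 (0.85) and Hal (0.67) higher and Arg1 (-1.06) lower. Of 18 circadian genes 8 rose and 2 fell (9 and 3 adjusted over the list alone), with Cry2 (1.44), Per3 (1.25) and Dbp (1.19) higher. Of 24 genes of heme synthesis and iron handling 3 rose and 7 fell, with the transferrin receptor Tfrc from 19.6 to 6.08 CPM (-1.68 ± 0.25) and Blvrb (-1.31) lower and Hmox1 (0.82) and Hjv (0.85) higher. Of 14 genes of the growth hormone and IGF axis 5 rose and 0 fell, among them Bcl6 (1.66), Cux2 (1.29), Stat5b (1.08) and Stat5a (1.01). Of 24 male-biased liver genes 5 rose and 6 fell, with Cyp2u1 higher and Cyp7b1 and Keg1 (-0.76) lower, and of 28 female-biased liver genes 2 rose and 10 fell, with Slc22a27 (-1.13), Sult3a1 (-1.32) and Cyp3a44 lower.

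Of 23 genes of ER stress 2 rose and 4 fell (2 and 2 adjusted over the list alone), with Trib3 (1.17) and Sel1l (1.03) higher and Dnajb9 (-1.09) and Manf (-1.02) lower. Of 25 acute phase genes 7 rose and 3 fell, with C3 (1.11) and Itih3 (0.74) higher and Orm1 (-1.58) and Orm3 (-1.25) lower. Of 29 interferon response genes 1 rose, Gbp2 (1.32), and 4 fell (3 adjusted over the list alone), with Isg15 (-1.28) and Bst2 (-1.12) lower. Of 21 cell cycle genes 1 rose and 4 fell, with Cdk1 (-2.05), Rrm2 (-1.66), Tyms (-1.07) and Pcna (-0.84) lower. Single markers of other liver cell types were called, while camera called none of the 5 lists that follow (adjusted p = 0.183 to 0.96). Kupffer cell and macrophage markers rose in 4 of 15 and fell in 0, with Marco (2.23), Csf1r from 10.5 to 31.0 CPM (1.56 ± 0.28) and Cd5l (0.92). Sinusoidal endothelial markers rose in 4 of 15 and fell in 0, with Cdh5 (1.18), Ptprb (0.92), Stab2 (0.90) and Stab1 (0.72). Lymphocyte and neutrophil markers rose in 3 of 12 (1 adjusted over the list alone), among them Cd79a (2.58) and Ighm (1.19). Stellate cell and fibrosis genes rose in 3 of 15 and fell in 2 (4 and 2 adjusted over the list alone), with Pdgfrb (1.45) and Ecm1 (0.90) higher and Lum (-0.93) and Dcn (-0.49) lower. Cholangiocyte markers rose in 3 of 9 and fell in 2 (4 and 4 adjusted over the list alone), with Krt23 (1.40) and Sox9 (1.39) higher and Spp1 (-0.69) lower. Stab1 (-0.37) and Spp1 (0.18) turned sign with the length and GC trend removed, as did Ptprb (-0.012), Stab2 (-0.16) and Pdgfrb (-0.22) with each library's length slope in the model. Of adipose, pancreas and muscle markers 2 were measured and 1 fell, Cela2a (-1.30), and 0 of 6 erythroid markers and 0 of 5 sex chromosome genes changed.

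Beside Cyp2e1, the largest female changes by the rule for named genes outside these lists were in genes of the major urinary protein cluster. The near-identical sequences of these genes make the split of reads between members uncertain. Mup19 was lower (-5.30 ± 1.55; 56.2 ± 84.3 CPM in wild type and 1.43 in knockout), as were Mup18 (-4.21 ± 1.07) and Mup16 (-3.64 ± 1.03; 540 ± 637 and 43.3 CPM), with a wide spread among the wild type libraries. Sult2a7 (-3.36 ± 0.57; 14.3 and 1.39 CPM) and Rec114 (-2.74 ± 0.82) were lower. Srp54b (3.53 ± 0.63; 0.695 and 8.05 CPM), a member of a family with near-identical copies, Ppargc1b (2.71 ± 0.53), Gse1 (2.60 ± 0.57) and Sptb (2.57 ± 0.40; 0.993 and 5.92 CPM) were higher. The laminin chain Lama3 was higher too, with a ratio of 7.59 (95% counting interval 2.60 to 36.8) since wild type females had 3 counts in all.

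The male comparison asked the same question in males. Knockout males had higher levels of 3 fatty acid omega-hydroxylase genes of the Cyp4a cluster on chromosome 4 and of Fdps, an enzyme of cholesterol synthesis, and lower levels of Glo1, which detoxifies methylglyoxal, and of the lipocalin gene Obp2a. Cyp4a14 (ENSMUSG00000028715, 115343397 to 115353339) rose from 0.705 ± 0.772 to 16.3 ± 5.84 CPM (4.44 ± 0.55, adjusted p = 0.00654). Cyp4a10 (ENSMUSG00000066072, 115375461 to 115390846) rose from 4.39 ± 2.21 to 30.5 ± 4.79 CPM (2.78 ± 0.33, adjusted p = 0.00497), and Cyp4a31 (ENSMUSG00000028712, 115420846 to 115436212) from 0.584 to 3.30 CPM (2.48 ± 0.34, adjusted p = 0.0112). Fdps (ENSMUSG00000059743, chromosome 3, 89000895 to 89009266) rose from 3.82 ± 0.42 to 12.3 ± 1.41 CPM (1.68 ± 0.22, adjusted p = 0.00755). Glo1 (ENSMUSG00000024026, chromosome 17, 30803910 to 30845845) fell from 633 ± 73.1 to 298 ± 16.9 CPM (-1.08 ± 0.15, adjusted p = 0.0128). Obp2a (ENSMUSG00000062061, chromosome 2, 25590055 to 25593338) fell from 70.0 ± 54.2 to 5.597 ± 2.62 CPM (-3.64 ± 0.52, adjusted p = 0.0139), with the wild type males at 42.2, 132 and 35.5 CPM. The lncRNA Gm10503 (ENSMUSG00000117786, chromosome 17, 31139312 to 31182194), chosen after its values were seen, had 0 counts in knockout males, at least 86.8-fold lower than in wild type males. It overlaps Glp1r on the opposite strand, so the origin of its reads is uncertain.

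With Cyp2e1 these were the 8 of 14003 genes called in males, 4 higher and 4 lower, and each changed by more than 2-fold. The quasi-likelihood test put 678 genes at an unadjusted p under 0.05, and DESeq2 called 34 genes. Cyp2e1, Cyp4a10, Cyp4a14 and Gm10503 were called with each male library left out in turn. Fdps was not called without wild type replicate 1 (adjusted p = 0.0613) or 3 (0.0520), Cyp4a31 without wild type replicate 1 (0.0516) or 3 (0.0768) or knockout replicate 3 (0.0506), Obp2a without knockout replicate 1 (0.116), and Glo1 without wild type replicate 1 (0.153) or 3 (0.0768) or knockout replicate 1 (0.0947) or 3 (0.114). The count of genes was 5 without wild type replicate 1 or 3, 18 without wild type replicate 2, 14 without knockout replicate 2, and 1, Cyp2e1, with the 6 male libraries fitted alone. With the replicate number as a block 6 of the 8 kept their call.

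The list of cholesterol biosynthesis stood higher in knockout males: 23 of 24 members had positive values with a mean of 0.64, and 1, Fdps, passed over all genes (8 adjusted over the list alone). Camera gave adjusted p = 9.75e-20, and adjusted p = 0.107 with an estimated correlation. Of 12 Cyp4 fatty acid hydroxylases 3 rose, the Cyp4a genes above (3 adjusted over the list alone; camera adjusted p = 1.14e-08; adjusted p = 0.107 with an estimated correlation). By fry neither cholesterol biosynthesis nor the Cyp4 list was called (adjusted p = 0.0856 for both). Cyp2e1 is in no list, and in the other 32 lists 0 genes were called over all genes in males. Of these, the mitochondrially encoded respiratory chain had 11 of 13 members with positive values (mean 0.52, camera adjusted p = 0.00263; adjusted p = 0.744 with an estimated correlation), and its call ended without wild type replicate 3 (0.0649). Of 14 genes of gluconeogenesis and fasting response 11 had negative values (mean -0.47, camera adjusted p = 0.00905; adjusted p = 0.733 with an estimated correlation), and the call ended without wild type replicate 3 (0.429) or knockout replicate 1 (0.064) or 2 (0.16). Of 15 genes of stellate cell and fibrosis 13 had positive values (mean 0.31, camera adjusted p = 0.0113; adjusted p = 0.733 with an estimated correlation), and the call ended without wild type replicate 2 (0.0655) or knockout replicate 1 (0.064) or 3 (0.133). The 37 PPARalpha targets, which share regulation with Cyp4a10 and Cyp4a14, had 17 members with positive values and a median of -0.02.

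The mean of both sexes asked which genes differed between the lines with the female and the male effect given equal weight. Glo1 was lower (-1.003 ± 0.11, adjusted p = 0.00109) and its neighbour Gm10503, 0 counts in knockout mice of both sexes, was lower (adjusted p = 2.16e-05). On chromosome 5, Hsd17b13 (0.75 ± 0.14), Hsd17b11 (ENSMUSG00000029311, 104137628 to 104169785; 1.002 ± 0.12, adjusted p = 0.00221), enzymes of lipid droplets, Nudt9 (ENSMUSG00000029310, 104194172 to 104213245; 0.92 ± 0.12, adjusted p = 0.00383) and Aff1 (103840240 to 104003188; 1.44 ± 0.21, adjusted p = 0.009) were higher. Cyp4a14 (2.40 ± 0.35), Cyp4a31 (1.85 ± 0.22), Cyp4a10 (1.41 ± 0.22) and Fdps (1.19 ± 0.15) were higher, Nlrc5 was higher (1.59 ± 0.16, adjusted p = 0.00107) and the acute phase gene Orm3 lower (-1.21 ± 0.15, adjusted p = 0.00383). Glo1, Gm10503, Hsd17b11, Nudt9 and Aff1 were chosen here after their values were seen. The call for Cyp4a10 ended without female knockout replicate 2 (0.0506). That for Hsd17b13 ended without female wild type replicate 1 (0.0568) or 2 (0.0643), female knockout replicate 2 (0.0603), male wild type replicate 1 (0.056) or 3 (0.0523) or male knockout replicate 1 (0.0549).

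Of 14003 genes 2111 changed over both sexes, 1090 higher and 1021 lower, 512 by more than 2-fold (385 higher and 127 lower). The balance was 1072 higher and 596 lower with a mean CPM of at least 5, and 482 and 870 with the length and GC trend removed. By the rule for named genes the largest changes were Neat1 (1.98 ± 0.40), Cyp4a31, Nlrc5, Zfp579 (1.54 ± 0.27), Syne1 (1.54 ± 0.20) and Depp1 (1.45 ± 0.19) upward and, beside Cyp2e1, Ddit4 (-1.37 ± 0.28), Spc25 (-1.28 ± 0.20), Tafa2 (-1.27 ± 0.38), Ppih (-1.25 ± 0.20) and Orm3 downward. By the quasi-likelihood test 5591 genes had an unadjusted p under 0.05 in the full fit, and 4107 to 7028 with 1 library left out. The count of called genes was 21 with each library's length slope in the model, and it depended on single libraries. Without female wild type replicates 1, 2 and 3 it was 47, 35 and 676, without female knockout replicates 1, 2 and 3 it was 356, 18 and 316, without male wild type replicates 1, 2 and 3 it was 27, 4510 and 72, and without male knockout replicates 1, 2 and 3 it was 32, 5594 and 58. In all 12 of these fits 17 genes were called: Aff1, Cyp2e1, Cyp4a14, Cyp4a31, Depp1, Fdps, Glo1, Gm10503, Hsd17b11, Nlrc5, Nudt9, Orm3, Syne1, the aminophospholipid flippase Atp8b5 (-1.98 ± 0.28), Dock6 (0.99 ± 0.14), Map3k1 (1.20 ± 0.18) and Srp54b (2.87 ± 0.43). With each library's length slope in the model 7 of the 17 lost their call: Aff1 (adjusted p = 0.0586), Atp8b5 (0.124), Dock6 (0.0835), Fdps (0.0539), Map3k1 (0.124), Srp54b (0.212) and Syne1 (0.0756), and Dock6 also lost it with the length and GC trend removed (0.142). Atp8b5, Dock6, Map3k1 and Srp54b were chosen after their values were seen, and each other gene named over both sexes lost its call in at least 1 of these fits.

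In the mean of both sexes 35 of 74 members of the nuclear-encoded respiratory chain fell and 0 rose (64 adjusted over the list alone), with Atp5k (-0.88), Atp5h (-0.71) and Ndufa5 (-0.71). Camera gave adjusted p = 1.34e-16, and adjusted p = 0.938 with an estimated correlation. In males alone 0 of the 74 were called, with a list mean of -0.08, against -1.13 in females. With each library's length slope in the model the mean of the nuclear-encoded respiratory chain was -0.043 (adjusted p = 0.394). Of glutathione S-transferases 3 of 20 fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.00837; adjusted p = 0.67 with an estimated correlation), with Gsta1 (-1.35), Gstm2 (-0.61) and Gstt1 (-0.40). The adjusted p of glutathione S-transferases was 0.27 with the length and GC trend removed. Length and GC content accounted for 27.1% of the variance of this effect across genes. Of 12 Cyp4 fatty acid hydroxylases 3 rose (3 adjusted over the list alone; camera adjusted p = 0.012; adjusted p = 0.815 with an estimated correlation). Of 24 genes of cholesterol biosynthesis 4 rose, among them Fdps, Srebf2 (0.93) and Lss (0.69), and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0362; adjusted p = 0.938 with an estimated correlation). That call ended without female wild type replicate 3 (0.103), female knockout replicate 1 (0.152), male wild type replicate 1 (0.117) or 2 (0.103) or male knockout replicate 2 (0.0795). The list means in females and in males were -0.64 and -0.02 for glutathione S-transferases. They were 0.09 and 0.83 for the Cyp4 list and -0.05 and 0.64 for cholesterol biosynthesis. In the other 30 lists camera made 0 calls, with members on both sides such as Cyp7a1 (-1.16 ± 0.24), Thrsp (-1.37 ± 0.26) and Nr1d1 (1.74).

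**Figure D3:**
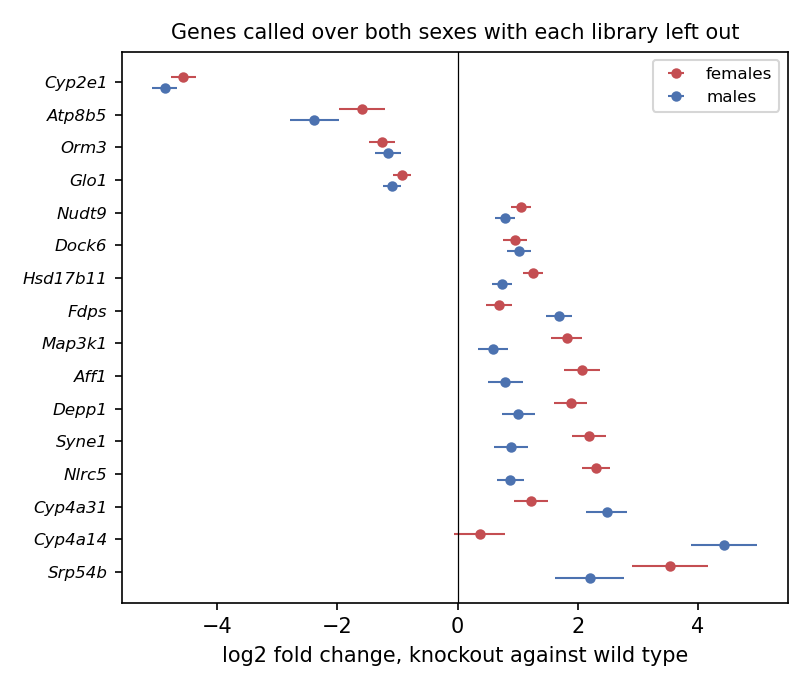
Knockout against wild type log2 fold change in females and in males of 16 of the 17 genes called over both sexes with each of the 12 libraries left out in turn, with bars of 1 standard error (Gm10503, at 0 counts in knockout mice, is not drawn). Of the 17 genes 7 lost their call with each library's length slope in the model. Glo1 lies at -0.92 in females and -1.08 in males, and Cyp4a14 at 0.37 in females and 4.44 in males.

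The difference between the sexes in the knockout effect was tested itself. The male effect exceeded the female effect by 2.75 ± 0.44 for Cyp4a10 (adjusted p = 0.123) and by 4.07 ± 0.69 for Cyp4a14 (adjusted p = 0.138), both chosen after their values were seen, and neither passed. Cyp4a10 passed without male wild type replicate 3 (adjusted p = 0.0261), without the 2 male libraries of lowest length slope (0.00595), with the length slope in the model (0.0314) and with no filter (4.04e-10). Cyp4a14 passed without male wild type replicate 1 (adjusted p = 0.0156), by DESeq2 (1.86e-06) and with no filter (9.21e-17). DESeq2 gave Cyp4a10 no adjusted p. The quasi-likelihood test called 0 of 14003 genes, with 3145 at an unadjusted p under 0.05. DESeq2 called 218 and gave no adjusted p to 12759 of the genes. Camera called 5 of 34 lists, each with a higher value in males. The nuclear-encoded respiratory chain differed by 1.05 on average (69 of 74 members positive, 54 adjusted over the list alone; camera adjusted p = 9.02e-19; adjusted p = 0.756 with an estimated correlation), and cholesterol biosynthesis by 0.70 (21 of 24 positive, 6 adjusted over the list alone; camera adjusted p = 1.54e-05; adjusted p = 0.756 with an estimated correlation). Glucuronidation, sulfation and acetylation differed by 0.83 (24 of 28 positive; camera adjusted p = 0.000336; adjusted p = 0.756 with an estimated correlation), glutathione S-transferases by 0.61 (18 of 20 positive; camera adjusted p = 0.00266; adjusted p = 0.488 with an estimated correlation) and drug and steroid P450s by 0.62 (30 of 42 positive; camera adjusted p = 0.0133; adjusted p = 0.756 with an estimated correlation). The call for drug and steroid P450s (Cyp1 to Cyp3 families) ended without female knockout replicate 1 (0.0702), male wild type replicate 3 (0.0882) or male knockout replicate 1 (0.113). Length and GC content accounted for 30.2% of the variance of this difference across genes. With that trend removed the adjusted p was 0.288 for glutathione S-transferases, 0.785 for glucuronidation, sulfation and acetylation and 0.769 for drug and steroid P450s (Cyp1 to Cyp3 families), whose mean difference was then 0.13 while camera pointed down.

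Across the 14003 genes, which are not independent replicates, the female and the male knockout effect correlated with Pearson r = 0.34 and Spearman rho = 0.39, and 65.4% of genes had the same sign. Among the 5116 genes called in females 78.2% had the same sign in males, and 5 of the 8 male calls were also called in females with the same sign. The correlation rested on male libraries: r was 0.048 without male knockout replicate 3, 0.0726 without male wild type replicate 3 and 0.582 without male knockout replicate 2.

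Male and female livers differed in both lines in the lists of male-biased and female-biased liver genes (adjusted p = 2.68e-07 to 5.85e-06 with an estimated correlation). In wild type mice Cyp4a12a, a male-specific fatty acid hydroxylase, stood at 0.0958 CPM in females and 640 CPM in males (12.62 ± 0.67, adjusted p = 6.6e-08), and the Y-linked Eif2s3y was at least 711-fold higher in males. Obp2a and the Y-linked Ddx3y had 1 count in all wild type females, with male to female ratios of 3634 (95% counting interval 652 to 143554) and 3594 (645 to 141947). A1bg had 0 counts in wild type males and was at least 14029-fold lower there than in females, as were Cyp3a41b (at least 9105-fold) and the sulfotransferase Sult3a2 (at least 7727-fold), and Sult3a1 had a female to male ratio of 123896 (22237 to 4893650). In knockout mice Cyp4a12a (11.86 ± 0.63), Cyp4a12b (at least 2162-fold), Ddx3y (at least 1199-fold) and Eif2s3y (at least 996-fold) were higher in males. Cyp3a41b (at least 3522-fold), Sult3a2 (at least 3108-fold) and Sult2a2 (at least 1420-fold) were lower there, and Sult3a1 had a female to male ratio of 25139 (6959 to 207580). Cyp3a41a and Cyp3a41b, Sult3a1 and Sult3a2, and Cyp4a12a and Cyp4a12b are near-identical pairs, so the split of reads within each pair is uncertain.

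In wild type mice 629 genes differed between the sexes, 294 higher and 335 lower in males, and in knockout mice 756 did, 413 higher and 343 lower. The balance in wild type mice depended on the processing. It was 509 higher and 386 lower with the length and GC trend removed, 635 and 591 by DESeq2, and 357 and 403 with each library's length slope in the model. The lines shared 172 of the genes higher in males, against 8.67 if independent, and 174 of those lower, against 8.21. Across all 14003 genes the sex difference in the lines correlated with Pearson r = 0.64 and Spearman rho = 0.03, and of 1039 genes called in either line 117 had opposite signs. The wild type count fell by more than 1.5 times without female wild type replicate 2 (379) or 3 (413). The knockout count did so without female knockout replicate 1 (440), 2 (467) or 3 (494) or male knockout replicate 1 (500) or 2 (502).

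Of 24 male-biased liver genes 23 were higher in males in each line (mean 4.91 in wild type and 4.97 in knockout; adjusted p = 2.74e-07 and 2.68e-07 with an estimated correlation), and of 28 female-biased liver genes 27 were lower in wild type and 28 in knockout males (adjusted p = 7.48e-07 and 5.85e-06 with an estimated correlation). Adjusted over the list alone these counts were 23 and 23, and 28 and 28. Sex chromosome control genes, 4 higher and 1 lower in males in both lines, also held with an estimated correlation (adjusted p = 0.00636 and 0.00434). In wild type mice drug and steroid P450s (8 higher, 14 lower of 42; adjusted p = 0.0107 with an estimated correlation) and glucuronidation, sulfation and acetylation (1 higher, 9 lower of 28; adjusted p = 0.0181 with an estimated correlation) held as well. In knockout mice the P450s had 10 higher and 13 lower (camera adjusted p = 1.66e-05; adjusted p = 0.0986 with an estimated correlation), and glucuronidation, sulfation and acetylation 7 higher and 8 lower (camera adjusted p = 2.82e-05; adjusted p = 0.255 with an estimated correlation). In both of these knockout lists the median member was positive (0.06 and 0.28) while the mean was negative (-1.44 and -1.77), as a few members had far larger negative values.

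Camera called 14 of 34 lists between the sexes in wild type mice and 16 in knockout mice, and the calls not yet given did not hold with an estimated correlation. Of all these camera calls, fry held 7 and lost 7 in wild type mice, and held 10 and lost 6 in knockout mice. PPARalpha targets (fry adjusted p = 0.000115 and 0.000498) and cell cycle genes (0.00854 and 0.0266) were among those held in both lines. ER stress (0.000498), glutathione S-transferases (0.000267) and the growth hormone and IGF axis (0.00203) were among those held in knockout mice. Genes of ER stress and integrated stress response were higher in knockout males in 6 of 23 (10 adjusted over the list alone; camera adjusted p = 0.000303; adjusted p = 0.119 with an estimated correlation). Glutathione S-transferases had 5 higher and 1 lower of 20 in knockout males (camera adjusted p = 0.000303; adjusted p = 0.0629 with an estimated correlation). The nuclear-encoded respiratory chain had 0 called genes in either line, with 66 of 74 members lower in wild type males (camera adjusted p = 0.000356; adjusted p = 0.81 with an estimated correlation; mean 0.024 and adjusted p = 0.674 with each library's length slope in the model) and 73 of 74 higher in knockout males (camera adjusted p = 5.76e-09; adjusted p = 0.598 with an estimated correlation). PPARalpha targets and fatty acid oxidation had 6 of 37 lower in wild type males (adjusted p = 0.0784 with an estimated correlation) and 7 in knockout males (adjusted p = 0.14 with an estimated correlation). Cell cycle genes had 3 of 21 lower in wild type males (adjusted p = 0.286 with an estimated correlation) and 2 in knockout males (adjusted p = 0.465 with an estimated correlation), and the growth hormone and IGF axis had 1 of 14 higher and 2 lower in knockout males (adjusted p = 0.14 with an estimated correlation). In wild type mice the calls for lipogenesis, cholesterol biosynthesis, mitochondrially encoded respiratory chain, circadian clock and output, stellate cell and fibrosis and erythroid markers (adjusted p = 0.623 to 0.81 with an estimated correlation) each ended without 1 or more libraries, and each of the 6 libraries ended at least 1 of them (adjusted p from 0.0545 to 0.831). In knockout mice the same held for cholesterol biosynthesis, acute phase response, Kupffer cell and macrophage markers, sinusoidal endothelial markers and erythroid markers (adjusted p = 0.511 to 0.648 with an estimated correlation; 0.0506 to 0.259 without single libraries). In wild type mice the mean of the mitochondrially encoded respiratory chain was 0.031 (adjusted p = 0.968) with the length and GC trend removed. Under the same setting the calls also ended for circadian clock and output in wild type mice (0.176) and for sinusoidal endothelial markers (0.0539) and erythroid markers (0.0751) in knockout mice. With each library's length slope in the model the same 4 calls ended (0.0806, 0.762, 0.057 and 0.14), as did that for cholesterol biosynthesis in knockout mice (0.0957).

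Genes near Cyp2e1 were compared with the rest, since a targeted allele kept in its own line can carry flanking DNA of another origin. Of 114 tested genes within 10 Mb on either side of Cyp2e1, 18 (15.8%) were called over both sexes, against 2092 of 13888 elsewhere (15.1%), an odds ratio of 1.06 (95% interval 0.60 to 1.77; two-sided Fisher's exact test, p = 0.793). No chromosome held an excess of called genes after adjustment. The smallest p was for chromosome 5, with 167 of 917 genes called (18.2%, odds ratio 1.28, two-sided Fisher's exact test, p = 0.00745, adjusted p = 0.164). The calls used here fell from 2111 to 21 with each library's length slope in the model. With the length and GC trend removed 1352 genes were called, 981 of them in both fits. The slope parted the female groups, so a model with it cannot tell a genotype effect from a difference between libraries. Most of the calls may follow either. Neither the comparison near Cyp2e1 nor that by chromosome can therefore show or exclude DNA of another origin.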

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

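Among the tests below, 3 were set before their results were seen. They are the r of the female effect with the length slope, the count of close pairs without a correction and the splits for the correlation between the sexes. The contrasts, the gene lists, the estimated correlation and the DESeq2 test were fixed before the data were examined. All others were chosen only after the result was seen.

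A tested difference between the sexes drew attention to 5 gene lists, each by camera with the preset correlation, and none of the 5 held with an estimated correlation (adjusted p = 0.488 to 0.756). The male effect exceeded the female effect on average by 0.62 for drug and steroid P450s (0.26 against -0.36), 0.70 for cholesterol biosynthesis (0.64 against -0.05), 0.61 for glutathione S-transferases (-0.02 against -0.64), 0.83 for glucuronidation, sulfation and acetylation (0.21 against -0.62) and 1.05 for the nuclear-encoded respiratory chain (-0.08 against -1.13). With the length and GC trend removed the mean difference of the P450 list was 0.13. In 75 of 100 splits that kept the sexes apart as many lists differed (5 in the real split, up to 15 in others), so chance cannot be excluded for their number.

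Female knockouts had 5116 called genes and male knockouts 8. A smooth trend in gene length and GC content as the whole cause is argued against by 3182 genes still called in females with it removed, 2486 of them called in both fits. A difference between libraries that also varies within groups may account for much of the female result: across genes the female effect correlated at r = 0.743 with the response to the length slope within the male groups, which share no library with it (0.616 after the trend was removed from both). A stronger response of females is open, since 0 genes differed between the sexes by the quasi-likelihood test, with 3145 at an unadjusted p under 0.05. DESeq2 called 218 genes and gave no adjusted p to 12759. Animals, handling and library preparation were not given beyond the group, so genotype and such a difference cannot be told apart in females.

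The 6 libraries of a sex allow 10 splits, too few for a share under 0.05. In females the real split called 5116 genes (1 of 10 with as many; highest other 0) and 3 lists (10 of 10; highest other 14). In males it called 8 genes (2 of 10; highest other 3647) and 5 lists (5 of 10; highest other 11). The split with 3647 genes set wild type replicates 1 and 3 and knockout replicate 2 against wild type replicate 2 and knockout replicates 1 and 3, which parts the male libraries by length slope and points to a structure of the male samples that genotype does not give. Between the sexes the real split called 629 genes (1 of 10; highest other 0) and 14 lists (1 of 10; highest other 13) in wild type mice, and 756 genes (1 of 10; highest other 0) and 16 lists (1 of 10; highest other 12) in knockout mice. For the mean of both sexes 5 of 100 splits called as many genes (real 2111, highest other 5965) and 80 of 100 as many lists (real 4, highest other 15). Chance cannot be excluded for the number of lists. For the genes the share of 5 of 100 does not exclude chance, but these splits cannot decide it. The 5 splits, the real one included, were among the 12 that kept the real grouping of the females, so they carry the female effect. The 88 that mixed the females called 0 genes. Chance cannot be excluded for the correlation of the effects either (19 of 100; real r = 0.34, highest other 0.65). For the number of genes that differ between the sexes the real count of 0 fixes the outcome (100 of 100 splits; highest other 4110, with the females in their real grouping), so the splits say nothing there.

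Cyp4a10, Cyp4a14 and Cyp4a31 were higher in knockout males. With the length and GC trend removed the smallest of the 3 changes was 2.57 (highest adjusted p = 0.0182), which argues against that trend. Reads moved among Cyp4a10, Cyp4a14, Cyp4a31 and Cyp4a32 are argued against by their sum, which rose from 14.5 ± 7.07 to 62.5 ± 6.02 CPM (log2 ratio 2.11). Cyp4a12a and Cyp4a12b together stood at 741 ± 195 and 727 ± 239 CPM. Their spread is wider than that rise, so reads moved from this pair stay open. Activation of PPARalpha, a candidate explanation, is open: the median of its 37 listed targets in males was -0.0185, with 17 above 0 and an SD of 0.313. Whether the lost enzyme or other DNA of the line is behind the change was not tested.

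Genes changed the same way in both sexes lay close together. At an unadjusted p under 0.01 in both sexes 53 genes had the same sign (3 had opposite signs). Among the 53 there were 9 pairs within 1 Mb of different gene families (first 3 letters of the symbol). In 10000 random draws the median was 2 and the 95th percentile 5 (permutation p = 0.0023). DNA that differs between the lines near those genes would give such pairs. The draws tested random placement only, so other reasons for neighbours to change together stay open. Pairs that share a gene are also not independent. The pairs were Glo1 with Gm10503 on chromosome 17, Creb3, Atp8b5 and Unc13b on chromosome 4, Nudt9 with Hsd17b11 and with Hsd17b13 on chromosome 5, and Leng8, Rdh13 and Zfp579 on chromosome 7. A length and GC trend as the whole cause is argued against by 10 such pairs among 71 genes chosen anew with it removed (median 4 and 95th percentile 8 in random draws, permutation p = 0.0197), but for 5 of the 9 pairs, which are not among the 10 and include those of chromosome 7, it stays open. A copy number difference of the segment with Glo1 (-1.003 ± 0.11) is open. The overlapping gene Dnah8 was not lower (0.38 ± 0.45), which a lower copy number of both genes does not predict. Its level of at most 0.614 CPM was too low to decide. Since the knockout allele and the line cannot be separated in this design, its share in these changes is open too.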

How the results depend on the processing

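The named-gene rule, the gene lists and the alternatives up to the replicate block and the libraries left out were fixed before the data were examined. Removing the length and GC trend, the length slope as a covariate, leaving out 2 male libraries, and leaving out single libraries for lists and for the correlation were added after seeing the data. With DESeq2 size factors 252 values of named genes and 47 of 47 of lists kept their direction and side of the threshold and 3 of named genes lost their call, and Cyp2e1 stayed between -4.69 and -4.02 in females and -4.94 and -4.78 in males under all alternatives. Replicate numbers do not pair the samples (3 of 18 pairs of libraries correlated above 0.1, range -0.61 to 0.28), and with the replicate number as a block the counts were 3365 in females, 23 over both sexes and 415 for sex in wild type, and the odds ratio near Cyp2e1 was 0. The DESeq2 Wald test called 34 genes in males, 3959 over both sexes, 218 for the difference between sexes, and 1226 and 1395 for sex in wild type and knockout; it gave no adjusted p to 551 genes in males and 12759 for the difference. With no filter the counts were 101, 3900, 1451, 1700 and 1694, and a mean CPM of at least 5 gave 485 for sex in knockout. Only the 6 male libraries gave 1 gene. With the length and GC trend removed 3182 genes were called in females (37.1% higher, against 48.5%) and 1352 over both sexes (35.7% higher, against 51.6%). With the length slope as covariate the counts were 10 in females, 17 in males, 21 over both sexes and 3 for the difference. Without the 2 male libraries of lowest length slope they were 4769 over both sexes and 6 for the difference. The cause was not tested, except that fewer samples enter the fits with libraries left out.

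Lists called numbered 0, 0, 0 and 0 in females, males, both sexes and the difference, and 5 and 3 for sex in wild type and knockout, with an estimated correlation. With fry they numbered 5, 0, 1, 8 and 10 in females, in males, for the difference and for sex in wild type and knockout. They numbered 5 in females and 9 over both sexes with the trend removed, and 11, 9 and 17 in females, over both sexes and for the difference with the slope as covariate. In males they numbered 8 with DESeq2 size factors and 8 without the 2 male libraries, where 2 of the 5 calls of the main fit were lost. The window of 20 Mb gave an odds ratio of 0.838, and only genes called in either sex gave a correlation of 0.523. Leaving out single libraries gave 4 to 4227 genes in females, 5 to 18 in males, 18 to 5594 over both sexes, 0 to 2 for the difference, 379 to 781 for sex in wild type and 440 to 953 in knockout. The lists then numbered 3 to 7, 4 to 8, 3 to 6, 4 to 10, 10 to 15 and 13 to 17 in the same order, and the correlation 0.048 to 0.582. Chromosomes with an excess numbered 0 in all settings run.

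The values that reversed, the cause of which was not tested, were these. With the length slope as covariate, in females: Abcc2 -0.12, Aldh5a1 -0.038, Cpt1a -0.023, Cyp4a10 -0.56, Orm1 0.064, Pdgfrb -0.22, Ptprb -0.012, Sel1l -0.0066 and Stab2 -0.16. Over both sexes Pdgfrb was -0.026, Btbd9 -0.26 and Reln -0.030, and the nuclear-encoded respiratory chain between the sexes in wild type was 0.024. With the trend removed, in females, mt-Atp8 was 0.038, Spp1 0.18, Stab1 -0.37 and Sult3a1 0.22, and glucuronidation, sulfation and acetylation 0.24. Over both sexes Btbd9 was -0.58 and Reln -0.017, the mean difference between the sexes for drug and steroid P450s (Cyp1 to Cyp3 families) was 0.13 while camera pointed down, and the mitochondrially encoded respiratory chain between the sexes in wild type was 0.031. Cyp4a10 in females, not called, ranged from -0.094 (without wild type replicate 3) to 0.144 (without wild type replicate 1) and was -0.027 without knockout replicate 2. Of 124 named female genes 89 kept their side of the threshold with the trend removed and 5 with the slope as covariate.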

Other observations

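Apart from Neat1, which the rule for named genes takes, the genes and values in this part were chosen after they were seen, and no explanation of them was tested. Over both sexes the nuclear lncRNAs Malat1 (1.12 ± 0.31, adjusted p = 0.0388) and Neat1 (1.98 ± 0.40, adjusted p = 0.0263), which are retained in the nucleus, were higher in knockout mice, and both lost their call in fits with single libraries left out, in the replicate block fit and with the length slope as a covariate. Beside Glo1 on chromosome 17, the lncRNA Gm50240 was lower (-1.21 ± 0.33, adjusted p = 0.0383; 0.630 with the length slope as a covariate), while Btbd9, whose start overlaps that of Gm50240 on the opposite strand, did not pass (0.17 ± 0.16, adjusted p = 0.443). With the length and GC trend removed Btbd9 stood at -0.58 (adjusted p = 0.0283), and the split of reads between these overlapping genes is uncertain since the strand setting is not given in the sources used here.

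Mitochondrially encoded genes held 2.23% to 7.31% of the counts of a library. The share was 2.47%, 3.16% and 7.31% in wild type females and 6.34%, 3.95% and 3.50% in knockout females. The number of genes with at least 1 count ran from 17367 to 19999, with the 3 knockout female libraries at 19509 to 19999. The 20 most abundant genes held 23.4% to 29.2% of the counts. Between replicates of a group the Pearson correlation of log2 CPM was 0.947 to 0.986.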
